A study of Vicia faba with 6 samples.

How the data were processed

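RNA was measured in leaves of faba bean (Vicia faba, a grain legume), variety Bachar, in 3 libraries of watered control plants and 3 libraries of plants left without water for 10 days. Groups and replicate numbers were taken from the sample titles. The labels describe 4 replicates of 10 pots for each treatment, and 3 libraries per group were analysed here. Nothing in the labels says which pots a library came from, so p-values measure only the spread between these samples, which may be technical. No genome was used here.

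Per the file headers, each deposited table lists assembled genes with a length, an expected count, an FPKM value (fragments scaled for the length of the assembled gene and the library total) and best hits in Nr, SwissProt, KEGG, KOG, InterPro and GO. The assembler, aligner and counting tool are not given in the sources used here. Expected counts, as deposited by the authors, are estimates that need not be whole; 36.0% were whole. FPKM values deposited by the authors were already scaled for length and library total, and no assembled gene was listed under 0.01 FPKM. One missing from a table was taken as 0. The names of the assembled genes look like those of the Trinity assembler and end with the name of a library: 45376 were named for a control library and 88421 for a stressed library. One plant gene can therefore be present as several near-identical assembled genes, and how reads that fit several of them were shared out is not given. No strand setting is given either, so reads of overlapping and antisense genes cannot be told apart.

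Expected counts were rounded to whole numbers. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors, filterByExpr with the group, and no covariate. An assembled gene was called higher or lower in stressed leaves at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Log2 fold changes are stressed over control, and their standard error (SE) was the fold change divided by the square root of the test's F. Normalised read counts (CPM, counts scaled to an equal library size with the TMM factors) are given as mean ± SD of 3 libraries. For an assembled gene at 0 in every library of a group, the fold is a lower bound. It was computed against a floor of 3 counts per library, worth 0.0866 CPM in control and 0.0634 CPM in stressed libraries. Such bounds cover counting error only.

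A total of 47 gene lists were written before the data were examined, as patterns matched to the description of the Nr best hit. The lists for arthropods, bacteria and vertebrates had 0 members. The other 44 lists were tested with camera (limma 3.58.1) at the preset correlation of 0.01 between genes, and again with an estimated correlation. GO terms and KEGG orthology groups with 10 to 500 tested members were tested the same way, against the 38786 tested assembled genes with a GO term or the 37768 with a KEGG orthology group. Library properties were compared by exact permutation tests, 2-sided, which with 3 against 3 libraries cannot go below p = 0.1.

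The genes named in the text follow a rule written before the data were examined. First come the 6 largest rises and the 6 largest falls among called assembled genes with a mean of at least 10 CPM in the higher group, no overlap between groups and an informative description. Second comes, from each list, the called member with the lowest p in the direction with more calls, at 5 CPM or more. Where the opposite direction held at least 3 calls, its member with the lowest p is added. The lists of other organisms, ribosomal RNA and transposons gave no names. The rule gave 86 assembled genes, of which part is named. Descriptions are those of the best hit and name a similar protein, often of another legume.

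The tests were tested on simulated data, with counts drawn from the real means and library sizes of the stressed against control comparison over 59418 genes. Of 100 genes simulated at a 2-fold change, edgeR gave 78 an adjusted p under 0.05 and called 44; of 100 at 4-fold it called 97. It called 7 unchanged genes. Limma called 41 and 95 with 12 false calls, and DESeq2 called 53 and 99 with 99 false calls. The changed genes were drawn only from those with a mean of 5 CPM or more, which 19000 of the 62781 tested genes reached. Few genes were changed, as many up as down, so recovery at low counts and a shift in scaling were not tested. Camera found the 1 changed set and called 0 of 20 unchanged sets, but the genes were simulated independently, so this does not test lists of correlated genes.

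Alternatives fixed in advance were other scalings (DESeq2-style factors, upper quartile, library totals only), the DESeq2 Wald test (DESeq2 1.42.0), limma on log2(FPKM + 0.1) and on log2(FPKM + 1), no low-count filter, a CPM of 1 in 3 libraries, the replicate number as a block, a test against the fold threshold (glmTreat), a length of at least 500 nt, and each library left out in turn. Chosen after seeing the data were counts summed over assembled genes that share an Nr best hit, the assembled genes listed in all 6 libraries, list members by SwissProt description, and terms tested against all tested genes, which had been run first by mistake. Depth was even: totals ran from 40217003 to 41130089 expected counts. The chi-square per degree of freedom between replicates of a group was 7.83 to 12.4, so no library was a second copy of another. Tables were made with Python 3.11.15 and pandas 2.3.3.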

Results

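Leaf RNA was compared between watered faba bean plants and plants left without water for 10 days, with 3 libraries in each group, to find which transcripts differed under drought. The control libraries held 40635911, 40678300 and 40217003 expected counts, and the stressed libraries 40725024, 40717540 and 41130089. The tables listed 133797 assembled genes in all, transcript contigs built without a genome, of which 62960 were listed in all 6 libraries. An Nr best hit was given for 69740 of them, to 35630 distinct proteins.

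Dehydrins and late embryogenesis abundant (LEA) proteins, which protect cell structures during drying, rose in stressed leaves. Of 41 tested assembled genes 30 were higher and 3 lower. Their median log2 fold change was 5.82, or 5.15 with genes at 0 in a group set at their bound. Transcripts of photosynthesis fell, with 84 of 158 assembled genes of photosystems and light harvesting (47 under library totals) and 32 of 61 of the Calvin cycle lower. Transcripts of chromatin and the cell cycle fell in 264 of 431 and rose in 40, and those of phenylpropanoid and flavonoid synthesis fell in 36 of 68. Cell wall loosening genes fell in 93 of 180. These 6 lists differed by camera and held with an estimated correlation of their genes.

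By edgeR's quasi-likelihood test, 13511 of 62781 tested assembled genes were higher in stressed leaves and 11489 were lower, and 54.0% of the calls were higher. Without the fold threshold, 18617 were higher and 17827 lower. Scaling by library totals alone moved the median log2 fold change of all tested genes from 0.11 to 0.55, a shift of 0.44. It gave 19786 higher and 8477 lower, or 70.01% higher. Limma gave 69.5% higher on log2(FPKM + 0.1) and 65.5% on log2(FPKM + 1). In alternatives chosen after seeing the data the share was lower. It was 46.9% with counts summed per best hit and 49.8% for the assembled genes listed in all 6 libraries. Changes are given on the TMM scale. For every named assembled gene, 3 of 3 stressed libraries lay beyond all control libraries in the direction given, which follows largely from the rule that chose them. Calls followed the library for which an assembled gene was named: of the higher ones 13089 were named for a stressed library, and of the lower ones 10391 for a control library. The first principal component held 83.3% of the variance and parted the groups, and the second held 5.99% and set control replicate 3 apart from the other control libraries. Libraries had correlations of log2 CPM of 0.949 to 0.965 within groups and 0.686 to 0.702 between them.

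By camera, 20 of the 44 lists differed, 4 higher and 16 lower. With an estimated correlation 6 of these held. Among the lists that did not hold, some had estimated correlations under the preset 0.01, from -0.026 to 0.002. These were ABA receptors, reactive oxygen enzymes, aquaporins, NAC factors, nitrogen assimilation and seed storage proteins. Their loss was thus not due to a higher correlation, and its cause was not tested. The other lists that did not hold had estimates above 0.01. Camera also called 6 to 16 lists in splits of the libraries that mix the groups but keep part of their difference, so the calls that did not hold are less certain. Dehydrins and LEA proteins held as higher, and photosystems, Calvin cycle, cell wall loosening, phenylpropanoids, and chromatin and cell cycle as lower. Members are assembled genes, and several can share a best hit. The 41 dehydrins and LEA proteins had 23 best hits, and the 158 of photosystems 79. Counts and p-values therefore do not stand for as many plant genes. With counts summed per best hit, camera called 17 lists, 5 higher and 12 lower. Adjusted over the list alone, 13 lists had other counts of calls, by at most 2 assembled genes, and these are given beside them. In all other lists the counts adjusted over the list alone were the same. Where scaling by library totals alone moved a count of calls by over 1.5 times, or ended or turned the balance of higher and lower, its counts are given beside the list. The median changed sign with the scaling in 13 lists, of which 2 were called.

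**Figure D1:**
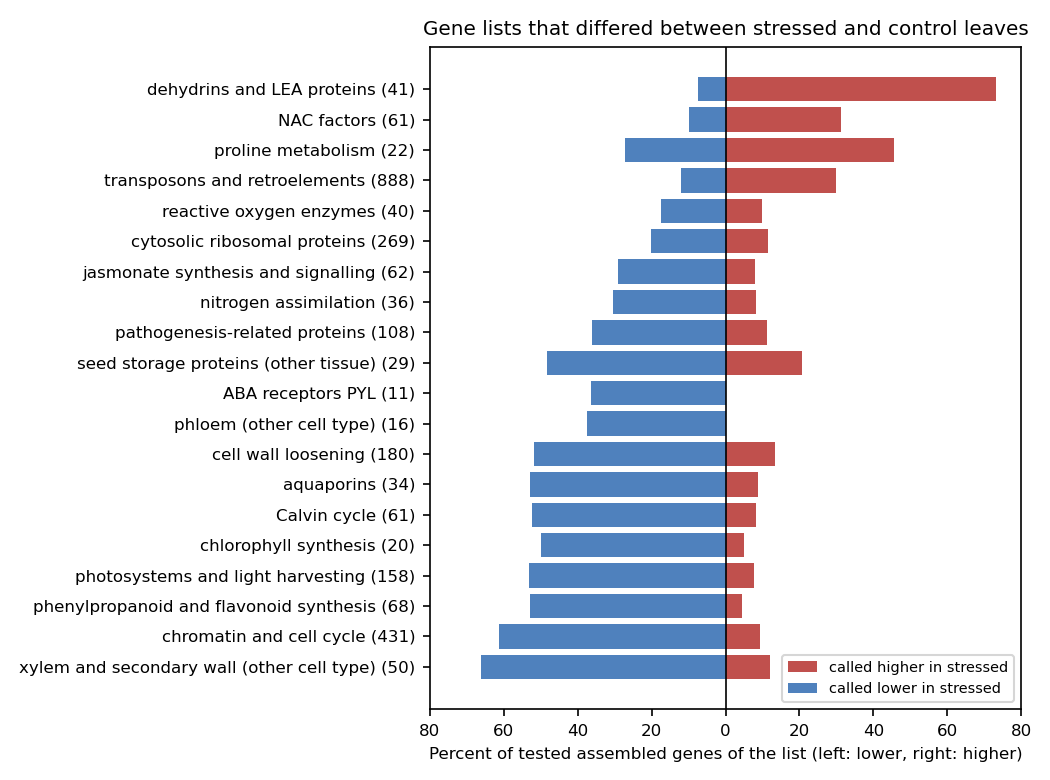
Share of tested assembled genes called higher (right) and lower (left) in stressed leaves, in percent, for the 20 lists that differed by camera, with the number tested in brackets. Dehydrins and LEA proteins had 30 of 41 higher, and chromatin and cell cycle 264 of 431 lower; the medians of the ABA receptor and reactive oxygen lists changed sign with the scaling, and under library totals the ribosomal and nitrogen lists had more higher than lower calls.

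Among the dehydrins and LEA proteins (camera adjusted p = 1.74e-52), dehydrin 2 (TRINITY_DN1807_c0_g1_i27-stressed_3) rose from 0.193 ± 0.0605 to 288 ± 11.5 CPM (SD, n = 3 per group), a log2 fold change of 10.52 ± 0.11 (SE; edgeR adjusted p = 3.8e-08), or 9.80 for the counts summed over its best hit. Desiccation-related protein PCC13-62 (TRINITY_DN10981_c0_g1_i1-control_2) fell, with a log2 fold change of -2.05 ± 0.10. In proline metabolism, 10 of 22 were higher and 6 lower (camera adjusted p = 0.00477; adjusted p = 0.148 with an estimated correlation; 1.77e-07 to 0.587 over all alternatives). Delta-1-pyrroline-5-carboxylate synthase isoform X1 (TRINITY_DN116_c0_g3_i1-stressed_2), the enzyme that commits glutamate to proline, rose from 18.4 ± 1.23 to 776 ± 33.2 CPM, a log2 fold change of 5.40 ± 0.07. A pyrroline-5-carboxylate reductase, which makes the last step to proline, fell with a log2 fold change of -4.57 ± 0.23, while the counts summed over its best hit had -0.04. The proline call was lost without stressed replicate 1 (adjusted p = 0.231), 2 (0.177) or 3 (0.162). It was also lost with limma on log2(FPKM + 0.1) (adjusted p = 0.587). Raffinose family and trehalose synthesis had 13 of 41 higher and 2 lower, or 14 and 3 adjusted over the list alone and 18 and 1 under library totals. It did not pass (camera adjusted p = 0.0548; 0.0456 without control replicate 1, and 0.0162 to 0.399 over all alternatives). A probable trehalose-phosphate synthase rose with a log2 fold change of 1.91 ± 0.06.

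Genes of abscisic acid (ABA), the hormone of drought signalling, moved in both directions. Abscisic acid 8'-hydroxylase 4 (TRINITY_DN1090_c0_g2_i3-control_3), which breaks ABA down, fell from 96.7 ± 0.951 to 6.39 ± 0.700 CPM (log2 fold change -3.92 ± 0.08). Abscisic acid 8'-hydroxylase OH2 (TRINITY_DN8691_c0_g1_i5-stressed_2) rose with a log2 fold change of 6.39 ± 0.32. The list of ABA synthesis and catabolism had 3 of 28 higher and 7 lower, or 7 and 7 under library totals, and did not differ (camera adjusted p = 0.527). Of the ABA receptors, 4 of 11 were lower. By edgeR 0 were higher, with 1 at an unadjusted p under 0.05, while DESeq2 and limma on log2(FPKM + 0.1) also called 0, and 1 was called under library totals. The list was lower (camera adjusted p = 0.0384; adjusted p = 0.174 with an estimated correlation; 0.00311 to 0.262 over all alternatives) with a median log2 fold change of -0.36 that turned to 0.07 under library totals. Without control replicate 2, control replicate 3, or stressed replicate 1, 2 or 3 its adjusted p was 0.0617, 0.0521, 0.124, 0.179 and 0.162. The receptor PYR1 (TRINITY_DN4401_c0_g1_i1-control_2) fell with a log2 fold change of -6.61 ± 0.19, or -2.01 for the counts summed over its best hit. Type 2C protein phosphatases are a family of which some members hold ABA signalling down, and the list took the whole family. Of these, 26 of 129 were higher and 27 lower, or 27 and 27 adjusted over the list alone. The counts were 26 and 25 with upper-quartile factors and 36 and 18 under library totals. Their share of counts was 0.222% in stressed and 0.151% in control libraries. The list did not differ (camera adjusted p = 0.892). Protein phosphatase 2C 51 (TRINITY_DN7121_c0_g2_i1-stressed_1) rose from 3.93 ± 0.338 to 157 ± 5.50 CPM, a log2 fold change of 5.32 ± 0.07. Probable protein phosphatase 2C 27 (TRINITY_DN4802_c0_g1_i1-control_2) fell with -2.30 ± 0.08. SnRK2 kinases and ABA-response bZIP factors had 5 of 49 higher and 6 lower, or 10 and 6 under library totals (camera adjusted p = 0.901). The kinase SRK2A fell with a log2 fold change of -4.79 ± 0.15, but its best-hit sum of -0.55 was not called. An abscisic acid-insensitive 5-like protein rose with 1.83 ± 0.09. A KEGG group named after its values were seen, ABA responsive element binding factors, had 10 of 20 higher and 0 lower (camera adjusted p = 0.00993, and 0.666 with an estimated correlation).

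NAC factors, transcription factors of which several act in stress and ageing, had 19 of 61 higher and 6 lower (camera adjusted p = 0.0278; adjusted p = 0.132 with an estimated correlation; 0.0502 without stressed replicate 1, and 0.000688 to 0.132 over all alternatives). NAC domain-containing protein 72 (TRINITY_DN17326_c0_g1_i7-stressed_2) rose from 6.25 ± 0.927 to 83.1 ± 2.05 CPM, a log2 fold change of 3.73 ± 0.10. AP2/ERF and DREB factors had 21 of 68 higher and 13 lower, or 21 and 14 adjusted over the list alone (camera adjusted p = 0.450). Dehydration-responsive element-binding protein 1A (TRINITY_DN49110_c0_g1_i1-stressed_3) rose with a log2 fold change of 4.25 ± 0.17. HD-Zip factors had 6 of 41 higher and 10 lower, or 7 and 10 adjusted over the list alone and 13 and 6 under library totals (camera adjusted p = 0.830). WRKY factors had 6 of 57 higher and 11 lower, or 13 and 5 under library totals (camera adjusted p = 0.967). MYB factors had 8 of 79 higher and 19 lower, or 12 and 13 under library totals and 9 and 6 in limma on log2(FPKM + 1) (camera adjusted p = 0.391).

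Ribulose bisphosphate carboxylase small chain 3A (TRINITY_DN6_c0_g1_i7-control_3), a subunit of the carbon-fixing enzyme Rubisco, fell from 7054 ± 192 to 1090 ± 34.9 CPM (SD, n = 3 per group), a log2 fold change of -2.69 ± 0.04 (edgeR adjusted p = 3.8e-08). The Calvin cycle list had 32 of 61 lower and 5 higher (camera adjusted p = 1.78e-31). In photosystems and light harvesting, 84 of 158 were lower and 12 higher, or 47 and 16 under library totals (camera adjusted p = 4.13e-25). Chlorophyll a-b binding protein of LHCII type 1 (TRINITY_DN69_c0_g1_i16-control_3), an antenna protein, fell with a log2 fold change of -4.10 ± 0.05, or -4.71 for its sum. An oxygen-evolving enhancer protein 2 (TRINITY_DN1047_c0_g3_i1-stressed_1) rose with 1.82 ± 0.05, or 1.16 for its sum. In chlorophyll synthesis, 10 of 20 were lower and 1 higher, or 6 and 1 under library totals (camera adjusted p = 1.89e-11; adjusted p = 0.0966 with an estimated correlation; 5.22e-21 to 0.0966 over all alternatives). A putative magnesium chelatase (TRINITY_DN448_c0_g1_i1-control_2), which puts magnesium into the pigment, fell from 4108 ± 165 to 907 ± 24.0 CPM. The list of senescence and chlorophyll breakdown had 9 of 34 higher and 5 lower, or 10 and 5 adjusted over the list alone. It did not differ (camera adjusted p = 0.810). In it, STAY-GREEN (TRINITY_DN246_c0_g2_i2-stressed_1), which starts chlorophyll breakdown, rose with a log2 fold change of 2.60 ± 0.06 and senescence associated gene 20 fell with -3.70 ± 0.06.

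Aquaporins, channels for water across membranes, had 18 of 34 lower and 3 higher, or 12 and 6 under library totals (camera adjusted p = 0.0158; adjusted p = 0.130 with an estimated correlation; 4.63e-08 to 0.130 over all alternatives). An aquaporin (TRINITY_DN92_c0_g6_i1-control_3) fell from 2326 ± 54.8 to 614 ± 9.89 CPM, a log2 fold change of -1.92 ± 0.03. Cell wall loosening genes had 93 of 180 lower and 24 higher, or 94 and 24 adjusted over the list alone and 78 and 37 under library totals (camera adjusted p = 1.17e-09). A probable xyloglucan endotransglucosylase/hydrolase (TRINITY_DN14216_c2_g1_i1-control_2) fell with a log2 fold change of -3.09 ± 0.07. A probable polygalacturonase (TRINITY_DN300_c0_g2_i1-stressed_3), which cleaves pectin, rose with 7.07 ± 0.13. Markers of xylem and secondary wall were lower with them, in 33 of 50 against 6 higher (camera adjusted p = 9.3e-06; adjusted p = 0.154 with an estimated correlation; 5.73e-09 to 0.154 over all alternatives). Those of phloem were lower in 6 of 16 and higher in 0 by edgeR, DESeq2 and limma, with 0 higher at an unadjusted p under 0.05 by edgeR. The phloem list was lower, with 3 lower calls under library totals, though its share of counts was 0.0992% in stressed and 0.0973% in control libraries (camera adjusted p = 0.00781, and adjusted p = 0.188 with an estimated correlation; 0.0580 under library totals, and 4.94e-05 to 0.188 over all alternatives). Fasciclin-like arabinogalactan protein 2-like fell with a log2 fold change of -2.10 ± 0.06 and SIEVE ELEMENT OCCLUSION B with -2.14 ± 0.08. Guard cell markers had 6 of 12 lower and 0 higher by edgeR, with 1 higher at an unadjusted p under 0.05, 0 by DESeq2, 1 by limma on log2(FPKM + 0.1) and 1 under library totals. They did not pass as a list (camera adjusted p = 0.214; 0.0219, 0.0205 and 0.0442 without stressed replicates 1, 2 and 3; 0.00853 to 0.705 over all alternatives). Potassium channel KAT1 fell with -1.70 ± 0.13. Cuticle and wax genes had 16 of 110 higher and 40 lower, or 26 and 30 under library totals, while their share of counts was 0.634% in stressed and 0.248% in control libraries (camera adjusted p = 0.107; 0.0447 without control replicate 1, and 0.00794, 0.00606 and 0.0135 without stressed replicates 1, 2 and 3, and 0.00166 to 0.554 over all alternatives). Among them an alcohol-forming fatty acyl-CoA reductase fell with a log2 fold change of -2.72 ± 0.07. Non-specific lipid-transfer protein 6 rose with 6.25 ± 0.12, or 5.42 for its sum.

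Chromatin and cell cycle had 264 of 431 assembled genes lower and 40 higher, or 265 and 41 adjusted over the list alone (camera adjusted p = 1.21e-19), with a median log2 fold change of -1.66. The 431 had 161 best hits, and the hit of histone H2A.1 alone had 56 tested assembled genes. Histone H2A.1 (TRINITY_DN1931_c0_g1_i6-control_1), a core histone, fell from 70.1 ± 3.52 to 3.27 ± 0.0732 CPM, a log2 fold change of -4.42 ± 0.06, or -2.15 for the counts summed over its best hit. Markers of meristem and young leaf had 4 of 56 higher and 15 lower, or 12 and 12 under library totals (camera adjusted p = 0.665). Cytosolic ribosomal proteins had 54 of 269 lower and 31 higher, or 54 and 32 adjusted over the list alone, and this turned to 35 lower and 44 higher under library totals, with a share of counts of 1.48% in stressed and 1.39% in control libraries (camera adjusted p = 2.85e-05; adjusted p = 0.205 with an estimated correlation; 0.0876 under library totals, and 4.23e-07 to 0.205 over all alternatives). The housekeeping list had 20 of 139 higher and 29 lower, or 33 and 22 under library totals (camera adjusted p = 0.246).

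Phenylpropanoid and flavonoid synthesis had 36 of 68 lower and 3 higher, or 37 and 3 adjusted over the list alone (camera adjusted p = 6.4e-13). Chalcone synthase 13 (TRINITY_DN27338_c0_g1_i1-stressed_3), the first enzyme of flavonoid synthesis, fell from 301 ± 9.68 to 38.4 ± 1.03 CPM, a log2 fold change of -2.97 ± 0.04. Pathogenesis-related proteins had 39 of 108 lower and 12 higher, or 40 and 13 adjusted over the list alone and 30 and 20 under library totals (camera adjusted p = 0.000187; adjusted p = 0.130 with an estimated correlation; 1.79e-05 to 0.130 over all alternatives). Pathogenesis-related protein 10a (TRINITY_DN748_c0_g1_i27-control_1) fell with a log2 fold change of -5.64 ± 0.10, or -1.02 for its best-hit sum. Jasmonate synthesis and signalling had 18 of 62 lower and 5 higher, or 11 and 8 under library totals (camera adjusted p = 0.0384; adjusted p = 0.323 with an estimated correlation; 0.0685 without stressed replicate 3; 0.119 under library totals, and 0.00427 to 0.323 over all alternatives). A putative linoleate 13S-lipoxygenase fell with -3.70 ± 0.06, or -1.41 for its sum. Ethylene genes had 11 of 45 higher and 7 lower, or 20 and 7 under library totals (camera adjusted p = 0.743), while their share of counts was 0.101% in stressed and 0.142% in control libraries. The ethylene-forming 1-aminocyclopropane-1-carboxylate oxidase 2 fell with a log2 fold change of -2.07 ± 0.06. Auxin response had 16 of 158 higher and 48 lower, or 27 and 27 under library totals, and did not pass (camera adjusted p = 0.214; 0.0379, 0.0327 and 0.0442 without stressed replicates 1, 2 and 3, and 0.0161 to 0.622 over all alternatives).

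Asparagine synthetase (TRINITY_DN3342_c0_g3_i1-stressed_3), which makes the nitrogen carrier asparagine, rose from 0.336 ± 0.0564 to 280 ± 7.79 CPM (SD, n = 3 per group), a log2 fold change of 9.69 ± 0.08 (edgeR adjusted p = 3.51e-08). Nitrate reductase (TRINITY_DN964_c1_g2_i2-control_2) fell from 363 ± 7.08 to 29.4 ± 1.30 CPM, a log2 fold change of -3.62 ± 0.05. The nitrogen assimilation list had 11 of 36 lower and 3 higher, which turned to 7 lower and 8 higher under library totals (camera adjusted p = 0.0158; adjusted p = 0.130 with an estimated correlation; 0.0530 under library totals, and 1.24e-05 to 0.130 over all alternatives). In starch and sucrose metabolism, 15 of 63 were higher and 16 lower, or 19 and 12 under library totals (camera adjusted p = 0.830). A beta-amylase, which breaks starch down, fell with a log2 fold change of -4.58 ± 0.06, or -2.00 for its sum, and beta-amylase 1 (TRINITY_DN673_c0_g6_i1-stressed_3) rose with 2.20 ± 0.03. Heat shock proteins had 42 of 136 higher and 23 lower, or 42 and 25 adjusted over the list alone and 51 and 13 under library totals (camera adjusted p = 0.403; 0.0156 under library totals, and 0.0156 to 0.945 over all alternatives). A heat shock 70 kDa protein (TRINITY_DN22455_c0_g1_i1-stressed_1), a chaperone, rose with 4.56 ± 0.06. Reactive oxygen enzymes had 4 of 40 higher and 7 lower, or 5 and 5 under library totals and 5 and 4 in limma on log2(FPKM + 0.1). The list was lower (camera adjusted p = 0.00175; adjusted p = 0.0900 with an estimated correlation; 0.160 under library totals; 1.24e-05 to 0.160 over all alternatives) with a median of -0.45 that turned to 0.01 in limma on log2(FPKM + 0.1). Glutathione S-transferases had 9 of 38 higher and 8 lower (camera adjusted p = 0.665). Autophagy and proteolysis had 21 of 117 higher and 14 lower, or 37 and 12 under library totals (camera adjusted p = 0.119; 0.0223 under library totals, and 0.0223 to 0.456 over all alternatives). Aspartic proteinase PCS1, a protein-cleaving enzyme, rose with a log2 fold change of 3.42 ± 0.05.

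**Figure D2:**
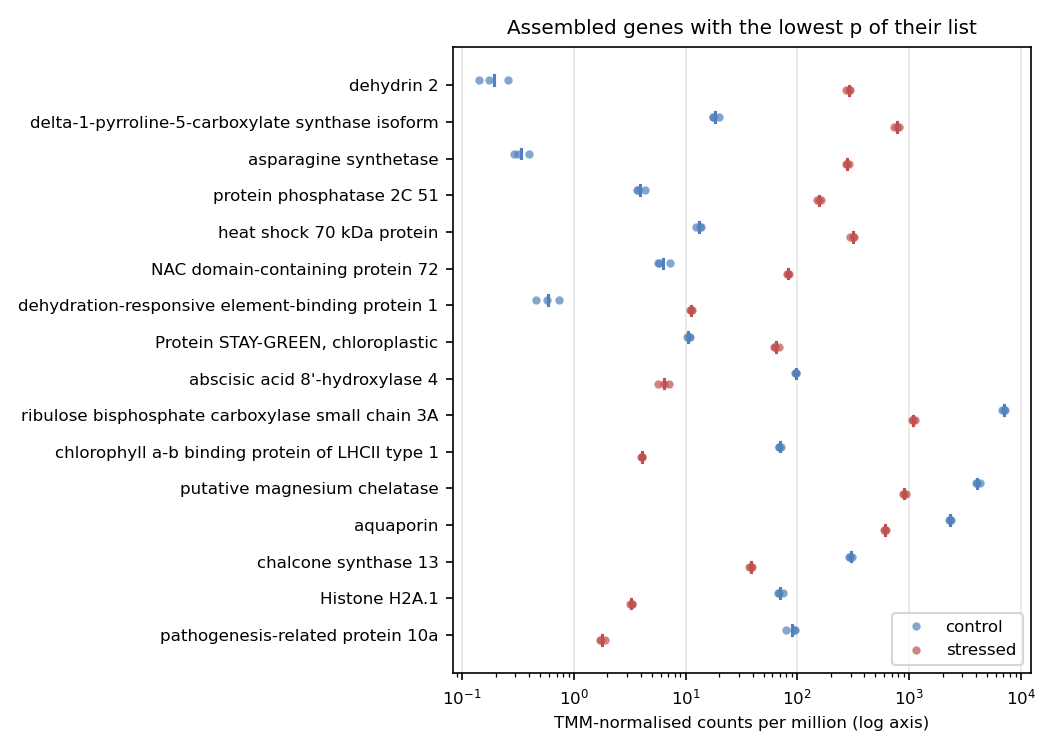
TMM-normalised counts (CPM) on a log axis for 16 named assembled genes; points are libraries, 3 per group, and bars are group means. Dehydrin 2 went from 0.193 to 288 CPM and ribulose bisphosphate carboxylase small chain 3A from 7054 to 1090 CPM.

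Transposons and retroelements had 265 of 888 higher and 108 lower, or 263 and 108 adjusted over the list alone and 434 and 89 under library totals (camera adjusted p = 0.0234; adjusted p = 0.323 with an estimated correlation; 0.160 under library totals; 0.000654 to 0.323 over all alternatives). Seed storage proteins, markers of another tissue, had 14 of 29 lower and 6 higher, or 12 and 10 under library totals (camera adjusted p = 0.0191; adjusted p = 0.132 with an estimated correlation; 0.185, 0.145 and 0.0803 without stressed replicates 1, 2 and 3, and 0.0145 to 0.815 over all alternatives). Members that moved were albumin-1, a small seed protein, with a log2 fold change of -5.23 ± 0.14 (-3.38 for its sum), and oleosin, a coat protein of oil bodies, with 1.55 ± 0.09. Nodule proteins had 8 of 23 higher and 7 lower, or 9 and 7 adjusted over the list alone and 4 and 5 in limma on log2(FPKM + 1) (camera adjusted p = 0.560). The list for organelle-encoded transcripts had 5 of 48 higher and 10 lower, or 7 and 5 under library totals (camera adjusted p = 0.476). It also caught proteins described as uncharacterized protein ycf45 isoform X1, and where its members are encoded was not checked. The ribosomal RNA list, which caught proteins that process ribosomal RNA, had 2 of 28 higher and 4 lower, or 2 and 0 in limma on log2(FPKM + 1) (camera adjusted p = 0.752). The virus list caught plant proteins and had 4 of 35 higher and 5 lower, or 8 and 1 under library totals (camera adjusted p = 0.597). The list of fungi and oomycetes had 1 of 11 lower (0 under library totals) and 0 higher by edgeR, DESeq2 and limma, with 0 higher at an unadjusted p under 0.05 by edgeR (camera adjusted p = 0.597). In none of the 20 called lists did the median, the mean and the camera direction differ in sign. They differed in the uncalled lists of ABA synthesis, type 2C phosphatases, SnRK2 and bZIP factors, starch and sucrose, glutathione S-transferases, senescence, AP2/ERF, nodule and organelle transcripts.

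The largest rises and falls under the rule were of assembled genes at 0 in every library of the other group, all with an edgeR adjusted p of 5.35e-05 or less. A contig described as actin (TRINITY_DN118_c1_g3_i3-stressed_1), a cytoskeleton protein, was at least 1276-fold higher in stressed leaves at 110.5 ± 9.25 CPM. Elongation factor Ts (TRINITY_DN1678_c0_g2_i2-stressed_3) was at least 895-fold higher and a probable polygalacturonase (TRINITY_DN300_c0_g2_i2-stressed_3) at least 674-fold. Starch branching protein I (TRINITY_DN656_c0_g2_i1-stressed_3) was at least 481-fold higher, sigma factor sigB (TRINITY_DN236_c0_g1_i4-stressed_1) at least 412-fold and alcohol dehydrogenase-like 2 (TRINITY_DN4946_c0_g2_i10-stressed_3) at least 405-fold. NifU-like protein 1 (TRINITY_DN276_c0_g2_i1-control_2) was at least 1781-fold lower and pseudo response regulator 37 (TRINITY_DN4004_c0_g1_i61-control_2), a clock protein, at least 950-fold. A UV-B-induced protein (TRINITY_DN626_c1_g1_i2-control_1) was at least 782-fold lower and pectinesterase (TRINITY_DN542_c0_g1_i19-control_2) at least 664-fold. UDP-apiose/xylose synthase (TRINITY_DN683_c0_g2_i1-control_2) was at least 590-fold lower and splicing factor SR45a (TRINITY_DN4691_c0_g1_i14-control_3) at least 566-fold. When counts were summed over all assembled genes with the same best hit, polygalacturonase and alcohol dehydrogenase-like 2 had smaller log2 fold changes of 6.50 and 8.13. Actin had no other tested assembled gene of its hit, so its sum tests nothing. Starch branching protein I had 1.31 and nifU-like protein 1 had -1.22, while elongation factor Ts went the other way with -1.01. The sums of sigB, pseudo response regulator 37, the UV-B-induced protein, pectinesterase, the synthase and SR45a were not called.

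**Figure D3:**
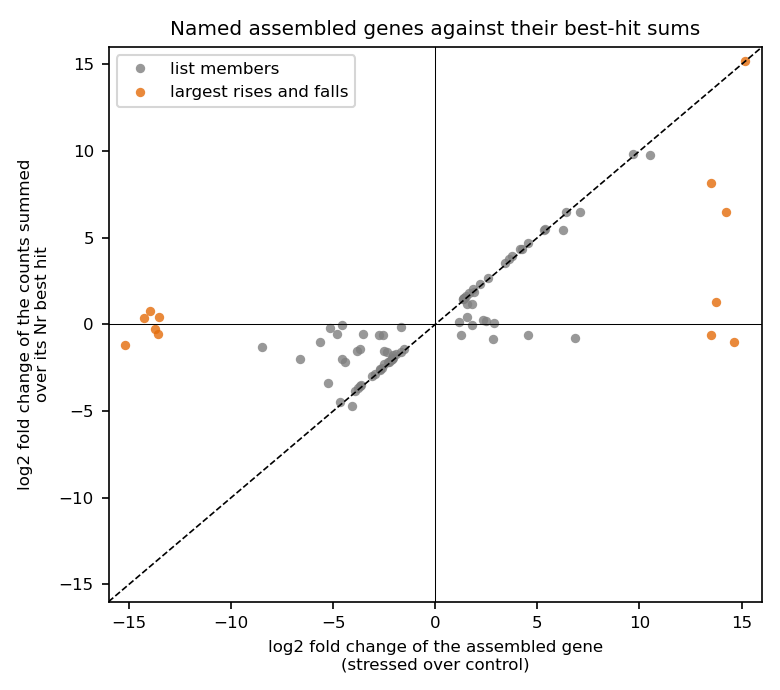
Log2 fold change (stressed over control) of the named assembled genes on the horizontal axis against that of the counts summed over their Nr best hit on the vertical axis; orange points are the 12 largest rises and falls, gray points are list members and the dashed line marks equal values. For 30 of the 86 the hit had no other tested assembled gene. Such a sum is no separate test, though its value can differ, as for asparagine synthetase with 9.81 against 9.69. Of the other 56, 32 had a sum called in the same direction and 10 had a sum of the opposite sign.

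Of 2869 GO terms and KEGG orthology groups, camera called 41 higher and 128 lower. With an estimated correlation camera called 0, where 190 had an unadjusted p under 0.05 and the lowest adjusted p = 0.144. The term for response to water had 15 of 17 tested assembled genes higher, and the KEGG group of delta-1-pyrroline-5-carboxylate synthetase 12 of 15 higher and 2 lower. The Rubisco small chain group had 21 of 22 lower, the group of light-harvesting complex II proteins 24 of 29, the nucleosome term 362 of 434, histone H4 84 of 89 and water channel activity 18 of 22. These terms share their subjects with lists given above and can hold the same assembled genes as the lists or as each other. They are therefore no separate test. Response to water had an adjusted p = 0.289 with an estimated correlation, the Rubisco, nucleosome and histone H4 terms 0.144, and light-harvesting complex II 0.436.

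More assembled genes were detected at 1 count or more in stressed libraries, 104275 ± 2430 against 91692 ± 2257 in control libraries (SD, n = 3 per group; exact permutation p = 0.1, the smallest possible). The 100 most abundant assembled genes held 20.5%, 20.6% and 20.1% of counts in stressed libraries and 29.4%, 29.6% and 30.1% in control libraries. Listed assembled genes were shorter in stressed libraries, with medians of 666, 652 and 630 nt against 711, 736 and 747 nt, and those with no Nr hit held 3.14%, 3.23% and 3.42% of counts against 1.91%, 1.86% and 1.90%. Every one of these differences had an exact permutation p = 0.1.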

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

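All tests in this part were chosen after the transcripts of stressed replicate 3 had been seen, and so was the list of animal protein families.

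Stressed replicate 3 held transcripts, flagged by their annotation, that the control libraries nearly lacked. Assembled genes with an animal protein family by InterPro held 905.3 expected counts there, against 1, 0 and 1 in the control libraries and 132 and 202 in the other stressed libraries. Of the 905.3 counts, 368.3 came from 1 assembled gene of the transgelin family, which the other stressed libraries held too. Assembled genes whose best hit was in Capsaspora, a unicellular relative of animals, held 3449 counts there and at most 36 in any other library. Assembled genes with a best hit to NPTII, a kanamycin resistance marker used in vectors, held 1620 counts there and at most 4 elsewhere. In all, 202 assembled genes with 17766 counts, 0.0432% of the library, were almost private to it, against 25 to 51 in each other library. By edgeR's filter 0 of the 202 were tested, so none entered the calls. That follows largely from their definition, by which the other libraries together held under 5% of the count in this one. Whether flagged assembled genes outside the 202 were tested was not counted.

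A greater depth of stressed replicate 3 is argued against by its total, which was 1.01 times the highest other total. RNA from animal cells may be the source, but the test did not decide it: animal families held 4.49 times the counts of the highest other library, between the 10 times set for that source and the 2 times set against it. The 132 and 202 counts of the other stressed libraries came almost wholly from 1 assembled gene of the transgelin family with a best hit in clover. That gene also held 368 of the counts in stressed replicate 3. It therefore sets the ratio of 4.49, which says little about the other families. The most abundant other families were intermediate filament proteins with 197 counts, fibronectin domains with 193 and nucleophosmin with 134, each at 1 count or less in any other library. No biological explanation was tested, since no group of the design sets this library apart.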

How the results depend on the processing

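Summing over best hits, testing the assembled genes listed in all 6 libraries, members by SwissProt description and terms against all tested genes were chosen after seeing the data. No called assembled gene was called in the opposite direction under any alternative on assembled genes, and of the 86 named ones, all but KAT1 (-0.74 in limma on log2(FPKM + 1)) and the higher ycf45 (1.18 with glmTreat) stayed called under every alternative fixed in advance that gave a value. Summed over the best hit, 10 changed sign: elongation factor Ts -1.01, sigB -0.59, pseudo response regulator 37 0.37, the UV-B-induced protein 0.79, SR45a 0.43, ascorbate peroxidase 6 -0.024, ribulose-phosphate 3-epimerase -0.61, PHAN1 -0.78, IAA8 -0.62 and fasciclin-like 15 -0.84. The sums include other assembled genes of the hit.

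The 25000 calls (13511 higher, 11489 lower) became 15960 with limma on log2(FPKM + 1), with 5510 lower. Test, scaling and pseudocount all differ there. Limma on log2(FPKM + 0.1) gave 8527 lower, and edgeR with library totals gave 8477. A CPM of 1 in 3 libraries tested fewer genes and gave 16153 (8655 and 7498), the assembled genes listed in all 6 libraries gave 8657 higher, and best-hit sums, with 26692 tested, gave 7740 (3629 and 4111). Leaving out 1 library gave 24167 to 26251 calls, 12343 to 14459 higher and 11460 to 11922 lower.

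Of the 20 called lists (4 higher, 16 lower), 6 held with an estimated correlation (1 and 5). The 4 higher lists became 2 with limma on either FPKM scale; the cause was not tested. Leaving out 1 library gave 19 to 22 lists, 2 to 5 higher and 15 to 17 lower. Of 44 lists, 21 had a changed call under an alternative fixed in advance, 9 with a library left out, and 0 reversed. The 41 higher and 128 lower terms became 0 and 0 with an estimated correlation and 229 lower against all tested genes, where the background differs by construction; leaving out 1 library gave 37 to 48 and 127 to 135. Detection at 10 counts gave a difference of 9057 assembled genes in place of 12583.

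The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.02, 0.01 and -0.01. With the replicate number as a block, 12034 were higher and 10844 lower, and 2 lists were higher. The MYB list was called, as lower, under the block alone (adjusted p = 0.0457).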

Other observations

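The terms in the next paragraph were named after their values were seen, and all tests below were chosen after the results they bear on were seen, except that of near-identical assembled genes, whose share was unseen though related sums had been looked at, and that of distinct best hits.

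Among the functional terms, the KEGG groups of HSP20 proteins and of 1 kind of splicing factor were higher in stressed leaves by camera. Neither these nor any other term given here passed with an estimated correlation. Several of the terms share their subject with a fixed list that did not differ. Examples are heat shock proteins (camera adjusted p = 0.403), ABA synthesis and catabolism (0.527) and SnRK2 kinases and bZIP factors (0.901). Small heat shock proteins of the HSP20 family, chaperones of unfolded proteins, had 28 of 62 tested assembled genes higher and 10 lower (adjusted p = 0.000882, and 0.776 with an estimated correlation), and the term for response to hydrogen peroxide had 23 of 40 higher and 6 lower. The term protein folding chaperone had 15 of 52 lower and 9 higher (adjusted p = 0.0129), and the cyclophilin B group 7 of 15 lower and 2 higher (adjusted p = 0.00536). Splicing factors of the arginine/serine-rich 1 group had 17 of 30 higher and 1 lower, and ABA responsive element binding factors 10 of 20 higher and 0 lower (adjusted p = 0.00993). The nerolidol synthase group had 20 of 38 higher and 3 lower and hydroxymethylglutaryl-CoA synthase 11 of 19 higher. Brassinosteroid biosynthetic process had 14 of 20 lower and xanthoxin dehydrogenase 11 of 16 lower. Carbonate dehydratase activity, which interconverts carbon dioxide and bicarbonate, had 26 of 40 lower and 7 higher, and catechol oxidase activity, of polyphenol browning, 13 of 19 lower and 2 higher. With an estimated correlation the adjusted p of the binding factors was 0.666.

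At a mean of 5 CPM or more, 242 assembled genes were listed in all stressed libraries and no control library and 167 the other way round, 409 in all, and 239 and 159 of these were named for a library of the group that listed them. Depth is argued against, since equal abundance would leave at least 171.5 counts in a library of the other group. Reads moved between near-identical assembled genes could account for part. Among 228 best hits with other tested assembled genes, those others moved the opposite way in 50.4% (95% Wilson interval 44.0% to 56.9%), which decides neither way, and in 45.5% of 2741 hits of other called genes. In 39.9% of the 228 hits they moved the opposite way by at least 0.5 times the CPM of the all-or-none genes. That share was not taken for other called genes, so it has nothing to be set against. Summed over best hits with other tested assembled genes, 37.1% of 272 all-or-none genes were called in the same direction, against 40.9% of 4408 other called ones. Plants of different genotype stay open, since the highest count in any mixed partition of the libraries was 1, which a drought response also gives.

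The higher number of detected assembled genes in stressed libraries stayed after thinning to the smallest total, with a difference of 12494, which argues against depth. Leaving out stressed replicate 3, the library with the flagged transcripts, left a difference of 11285 in listed assembled genes, which argues against RNA of another organism in it as the cause. Distinct Nr best hits differed by 3.22% (32262 against 31256) where assembled genes differed by 13.7%. This met the limit set for more sequences of stressed libraries in the reference set. However, the 13.7% includes assembled genes with no Nr hit, which cannot add a best hit. A hit was given for 57.2% of listed assembled genes in stressed and 61.3% in control libraries. The percentages compared are therefore unlike and do not decide this explanation. A wider transcription under drought was not tested apart from it.

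The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05, and 1 of the 10, the real one, gave the most calls in each test. The real split called 25000 assembled genes by edgeR and the highest other 0. For lists by camera the real split called 20 and the highest other 16, and for terms 169 and 50.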
